A study of Spodoptera frugiperda with 21 samples.

How the data were processed

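Libraries were made from whole 3rd-instar larvae, uninfected or infected with SfAV-1a, and per the labels' protocols each larva was homogenised separately, the RNA was treated with DNase and polyadenylated RNA was enriched before directional library preparation. The labels number 3 libraries in each of 7 groups, 21 in all. Replicate 3 of every group is listed in a separate block after replicates 1 and 2 of all groups, and may be another batch. The deposited means and SDs pool it with the others, so a batch difference enters the SDs and the bounds below and was not testable from means. Per the series' design text, sequencers of 2 models, an Illumina HiSeq and a NextSeq, were used, and which library ran on which is not given in the sources used here. Trimmomatic, Bowtie2 and RSEM are named per the submitters' processing notes, without versions. The mitochondrial genome and the gene model set are named per the file headers, and no build is given in the sources used here.

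The authors deposited 3 tables of mean TPM with the SD of TPM per group, and 3 of p-values per time against the uninfected group. TPM is a transcript's share of a library scaled to a sum of 1000000, and per the values the authors' mitochondrial table was scaled within its own 38 features, since each group sums to 1000000. The cytoskeleton and innate immunity means sum to between 17349 and 31757 TPM and between 4125 and 11356 TPM per group, so these are parts of larger tables not used here. In all 3 tables every deposited mean, multiplied by 3, is a whole number of hundredths (within 0.02 of a hundredth), 266, 742 and 679 values, as for means of 3 libraries. The SDs are the authors', and the values of single libraries and the read depth are not analysed here. The authors' p-values are deposited with 3, 2 and 4 decimals in the mitochondrial, cytoskeleton and innate immunity tables, a deposited 0 is a value below that rounding, and the test, its tool and any adjustment are not given in the sources used here. Many p-values repeat within a column, as step-up adjustment leaves them, so the adjustment applied here may be a second one.

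The design fixed before the data were examined planned limma on library values and, where tables held means only, the ratio of the means with the authors' SDs and p-values, and the second course was taken. The change is log2 of (mean TPM + 1) infected minus uninfected, a scale that understates low genes, and folds are ratios of the means without the pseudocount. A gene is called where the deposited p is under 0.05. Called genes were also counted after Benjamini-Hochberg adjustment over the table, and over each fixed list alone. A deposited 0 was adjusted as exactly 0. At the 2 decimals of the cytoskeleton p-values, the genes that pass over the table are those deposited as 0. With unrounded p-values some of them might not pass. Since the median ratio of a table drifts from 1 at late times, a called gene is said to have risen or fallen only if its log2 change lies beyond both 0 and the median of the table's tested genes. TPM values are compared only within a table, while the closing section compares, between 2 tables, the ratios about which their p-values are arranged. The cytoskeleton table of p-values lists 48 h before 24 h, and its headings were followed. As headed, p falls with distance from the best centre of the log2 changes with rank correlations of -0.826 at 24 h and -0.775 at 48 h, and with the 2 columns exchanged these are -0.261 and -0.253. The spread between libraries of a group is that between larvae, as the labels describe them. How a deposited p for 3 libraries against 3 weighs that spread is unknown, because the test is not given.

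Bounds on the 3 library values follow from their mean and SD: none can lie more than 1.15 SDs from the mean, and 0.005 was added to each SD for rounding. Where the bounds of 2 groups are disjoint, every library of 1 group lies beyond every library of the other, which chance gives in 10% of genes where library values are known. The same 2 numbers give the least share of the group's TPM that its highest library can hold and the range of the mean of the other 2. These steps, which were added after the data were seen, were tested on simulated data for 20 runs each with lognormal spread set to the median SD over mean of the uninfected group. They gave 0 wrong separations, as exact bounds must, so that number checks only the code. They found 37.6% and 97.0% of 2-fold and 8-fold changes over 103 cytoskeleton genes and 44.6% and 99.1% over 96 innate immunity genes. With no change 6.12% and 4.58% of genes separated. Python 3.11, NumPy, SciPy and matplotlib were used.

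Genes are named by the names the tables give; 0 of 106 and 0 of 97 identifiers were found in the reference gene table at hand, so no coordinates are given. Names that occur on several gene models (PGRP, Cactus, SR-B3, Hdd23, the eater models, dystonin, non-muscle myosin and the CecB genes) may share reads, and their values are uncertain. Gene lists were fixed as kinds of names before the data were examined and matched to the names in the tables afterwards, and 15 of them have measured members: the mitochondrially encoded genes (15), complex I (7), complexes II to IV (4), ATP synthase (2), microtubule motors and tubulin (64), actin and other cytoskeleton (40), antimicrobial peptides (16), lysozymes (5), recognition proteins (17), Toll (14), IMD and JNK (9), JAK-STAT (5), melanisation (6), hemocyte markers (2) and a muscle marker (1). The lists of mitochondrial import, chaperones, dynamics and transcription, apoptosis, protease inhibitors, RNA interference and oxidative stress had no measured member. The short names Gal, counted with the recognition proteins, and Hem, placed in no list, could each stand for members of more than 1 list. The tables were themselves chosen by the authors, so a list's share of called genes has no genome-wide background. Named genes are every mitochondrially encoded gene, the 5 greatest rises and 5 greatest falls among called genes of each table and time, up to 4 members per list of 3 or more by greatest change, and the 3 genes of highest uninfected mean per table, less those left out for length. Outside this rule, CYLD, AttB1, Myd88, Pelle, Dl, the Toll receptors, TEP3, Def-like6, CecC, CecD, Spodoptericin, actin-related protein 2, KIF18A and others named to complete a count or at further times were named after their values were seen.

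Alternatives were adjusted p-values, a p under 0.01, genes with a mean TPM of at least 5 in 1 of the groups, pseudocounts of 0.1 and 0 and division by the table's median ratio. Added after the data were seen were called genes with separated libraries, genes whose SD does not exceed the mean, and the count over times without 48 h. No column of library values was left unused.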

Results

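RNA was sequenced from whole 3rd-instar larvae of the fall armyworm, Spodoptera frugiperda, a moth whose caterpillars are a crop pest. Larvae were uninfected or had been infected with the ascovirus SfAV-1a, a DNA virus of caterpillars that breaks host cells into virus-filled vesicles. The 21 libraries form 7 groups of 3: uninfected larvae and larvae at 6 h, 12 h, 24 h, 48 h, 4 days and 7 days after infection. The authors' deposited tables give, for each group, the mean and SD of the relative abundance (TPM, transcript shares scaled to a sum of 1000000) over its 3 libraries, for 38 features of the mitochondrial genome, 106 cytoskeleton genes and 97 innate immunity genes. Every comparison sets 1 infected group against the uninfected larvae, and asks how these host genes changed as infection proceeded. The uninfected group is the only one without virus, so time after infection and age of the larvae run together in all 6 comparisons. Values below are the authors' mean TPM ± their SD over 3 libraries, and a gene is said to have risen or fallen only where the authors' deposited p-value was under 0.05 and its ratio lay beyond both 1 and the median ratio of its table. At late times the deposited p-values are arranged about raised ratios, as the closing section sets out. A fall at a ratio near 1 may then mean only that a gene moved otherwise than its table. The sequencing depth per library is unknown from these tables.

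Innate immunity genes at 6 h were mostly unaltered by the deposited test, with 2 genes risen and 3 fallen of 97. The antimicrobial peptide Moricin-1 went from 5.13 ± 2.78 to 33.5 ± 23.9 TPM, a 6.52-fold rise for which the authors' deposited p was 0.0004. It was the only gene at this time below 0.05 after Benjamini-Hochberg adjustment over the table (adjusted value 0.0388), and the scavenger receptor SR-B3 (GSSPFG00016871001.3) was the other that rose, from 18.8 ± 4.76 to 29.1 ± 5.08. DNR1, known in flies as a repressor of the IMD pathway, fell from 66.1 ± 3.98 to 38.4 ± 6.51 TPM, and Sick and the Toll-interacting protein Tollip fell 2.01-fold and 1.67-fold. The median log2 change of the table was -0.10.

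At 12 h, 11 immunity genes rose and 9 fell. Antimicrobial peptides made up most of the rise, with 7 of 16 measured members risen, 0 fallen and 9 not past the threshold. CecA rose 4.78-fold to 189 ± 205 TPM, CecB1 6.2-fold to 170 ± 165, CecB2 4.38-fold to 125 ± 112 and CecB3 6.6-fold to 254 ± 319. These cecropin SDs are about as large as the means, and the highest of the 3 libraries must hold at least 57.6% of the group's CecB2 and at least 80.3% of its CecB3, where the uninfected group gives at least 49.3% and 65.8%. CecB1, CecB2 and CecB3 bear like names and may have shared reads, which was not checked, so their separate values are uncertain. Moricin-1, at 30.1 ± 12.1 TPM, had all 3 infected libraries above all 3 uninfected ones by the bounds that mean and SD set. Of 17 recognition proteins 2 rose, among them the phagocytosis receptor Nimrod, from 55.0 ± 13.2 to 217 ± 204 TPM.

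The genes that fell at 12 h included signalling components. Genes of the AP-1 transcription factor fell, c-jun from 253 ± 48.1 to 139 ± 12.3 TPM and the Fos homologues Kayak and kayak 1.78-fold and 1.67-fold, which are the 3 of 9 members of the IMD and JNK list that passed. Tollip fell 2.01-fold and the adaptor Myd88 1.41-fold, 2 of the 14 Toll pathway genes. PPAE2, a prophenoloxidase-activating protease, fell from 38.5 ± 5.83 to 21.2 ± 1.13, and LLP1, counted with the lysozyme-like proteins, fell 4.56-fold from 98.0 ± 72.0 TPM. Adjusted over the table, 13 of the 20 called genes stayed below 0.05. Of the antimicrobial peptides 6 passed when adjusted over the list alone and 5 when adjusted over the table, and of the IMD and JNK genes 1 passed either way.

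At 24 h, 4 immunity genes rose and 7 fell, and the table's median log2 change was -0.19. Moricin-1 rose 15.6-fold, and Moricin-7 went from 0.657 ± 0.380 to 9.21 ± 5.55 TPM. Both had every infected library above every uninfected one. They were the only 2 of the 16 antimicrobial peptides that rose, while CecA, at 28.3 ± 11.4 TPM, was not called. Among peptidoglycan recognition genes, which bear the shared name PGRP, GSSPFG00006046001.5 fell 6.12-fold and GSSPFG00026857001.5 fell 3.01-fold, whereas GSSPFG00017964001.4 rose 27.8-fold to 2.78 ± 2.26. DNR1 fell to its lowest group mean, 31.9 ± 0.920 TPM. PPAE2 fell 2.01-fold and LLP1 5.01-fold. Adjusted over the table, 5 of the 11 called genes passed: both moricins, DNR1, PPAE2 and GSSPFG00006046001.5, the last being 1 of the 3 called recognition proteins.

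At 48 h, 16 immunity genes rose and 15 fell, of 95 with a deposited p. Gloverin-3, a glycine-rich antibacterial peptide of moths, rose 23.5-fold to 56.9 ± 30.6 TPM, Moricin-1 rose 19.7-fold to 101 ± 66.3 and Lebocin-1 rose 10.7-fold to 17.5 ± 9.37. Another lebocin, listed as Lebocin, went from 1.43 ± 1.34 to 122 ± 124 TPM, and its mean at the other 5 times lay between 0.770 and 2.62. Its SD at 48 h exceeds the mean, and the bounds did not separate its libraries from the uninfected ones. In all, 8 of 16 antimicrobial peptides rose and CecB2 fell 2.23-fold. Spodoptericin, outside that list, rose 6.45-fold to 480 ± 103. In the Toll list 4 of 14 members rose: both gene models of Cactus, the inhibitor of the NF-kappaB factor Dorsal, went from 73.2 ± 15.5 to 212 ± 113 and from 73.5 ± 17.7 to 221 ± 134 TPM, and the kinase Pelle and the ubiquitin ligase Pellino rose 2.48-fold and 2.32-fold. Dl, Toll-18w and Toll-E fell, Dl 1.39-fold. The 2 Cactus models have nearly equal values throughout and may share reads.

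Both prophenoloxidases, zymogens of the melanin-forming enzyme that are made in hemocytes, fell at 48 h. PPO2 went from 164 ± 74.8 to 46.0 ± 51.2 TPM and prophenoloxidase subunit 1 from 52.3 ± 38.9 to 16.2 ± 20.3. GBP-BP fell 2.75-fold beside them. The 2 prophenoloxidases are the only genes counted in the hemocyte marker list. Hem, an ambiguous name left out of it, stood at 11.9 ± 1.44 TPM at 48 h against 11.8 ± 3.08. Of the 5 lysozymes 3 fell, and Lys3 did so by 3.80-fold. Only 10 of the 31 called genes passed when adjusted over the table. Among those that did not were both prophenoloxidases, GBP-BP and the 3 lysozymes. The lysozymes passed when adjusted over their list alone, as did both prophenoloxidases over the hemocyte list of 2 genes. Over the melanisation list of 6, which also holds the prophenoloxidases, 2 of 3 called genes passed, and prophenoloxidase subunit 1 did not. Of 9 called antimicrobial peptides 5 passed over the table, and of the Toll list 1 passed that way but 5 when adjusted over the list alone. The median log2 change of the table was 0.33.

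At 4 days, 21 immunity genes rose, 19 fell and 1, CYLD, was called at a ratio between 1 and the table's median. Moricin-1 reached 303 ± 124 TPM, 59.0-fold above uninfected larvae, and Moricin-7 36.2 ± 17.8, a 55.1-fold rise. Lebocin-2 rose 14.4-fold to 97.0 ± 38.8, Gloverin-3 19.1-fold and Def-like6 4.74-fold to 663 ± 102, and CecC, listed at 0 in uninfected larvae, stood at 5.83 ± 4.61. These were among 7 of 16 antimicrobial peptides that rose, against 1, CecB3, that fell. Hdd23 (GSSPFG00027451001.3) rose 11.8-fold to 847 ± 267 TPM. Of 17 recognition proteins 5 rose, both SR-B3 models, SR-C1, Nimrod and a PGRP, and TEP3 fell. Nimrod stood at 256 ± 54.4.

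The falls in prophenoloxidase were deepest at 4 days. PPO2 stood at 10.8 ± 5.59 TPM, 15.2-fold below uninfected larvae, and prophenoloxidase subunit 1 at 3.35 ± 2.30, 15.6-fold below, with every infected library below every uninfected one for both. GBP-BP fell 8.70-fold. In the Toll list both Cactus models and the ligand Spz rose, the last from 9.69 ± 2.84 to 36.8 ± 18.3, and 4 members fell: Dl, Tl-like, Toll-18w and Toll-F. Adjusted over the table, 33 of the 41 called genes passed, and adjusted over the list alone 8 of 8 called antimicrobial peptides, 6 of 7 Toll genes and 3 of 3 melanisation genes did. The recognition proteins went from 6 called to 3 adjusted over the table and 1 adjusted over the list alone, and of 2 lysozymes and of 2 IMD and JNK genes 1 each passed over the list alone. The table's median log2 change was 0.50.

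At 7 days, 58 of 97 immunity genes were called. By the ratio of means 45 were higher and 13 lower, and after dividing by the table's median ratio, a log2 shift of 0.93, 27 were higher and 31 lower. Adjusted over the table, 55 of the 58 passed. The 27 that rose on both counts include 9 of 16 antimicrobial peptides: Moricin-1 at 229 ± 97.2 TPM, Lebocin-2 at 136 ± 79.7, Gloverin-3 at 103 ± 54.8, CecD at 68.9 ± 41.3 and Def-like6 at 816 ± 37.8, which are 44.7-fold, 20.2-fold, 42.5-fold, 13.9-fold and 5.83-fold above uninfected larvae. The attacins were not called, AttB1 being at 20.1 ± 11.5 TPM against 17.9 ± 8.76. SR-C1 rose 11.3-fold to 128 ± 15.2, Nimrod 8.42-fold to 463 ± 112 and Hdd23 (GSSPFG00027451001.3) to 1512 ± 232 from 72.1 ± 23.3. Lys2 rose 5.91-fold, and the hemolymph protease HP8 rose 4.12-fold to 277 ± 95.5.

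LLP1, PPO2, prophenoloxidase subunit 1 and GBP-BP were lower at 7 days by 3.73-fold, 3.94-fold, 3.38-fold and 1.78-fold. The 2 prophenoloxidase SDs were then larger than the means, 41.6 ± 48.8 and 15.4 ± 17.9 TPM. The Toll members that fell, 6 of 14, were Dl and the receptors Tl-like, Toll-18w, Toll-B, Toll-E and Toll-F, by 1.18-fold to 2.97-fold. Toll-18w, Toll-B, Toll-E and Toll-F were low in uninfected larvae, at 1.69 ± 0.34, 2.81 ± 1.14, 0.613 ± 0.04 and 2.51 ± 0.67 TPM. At 7 days Toll-18w, Toll-B and Toll-F stood at 1.44 ± 0.21, 2.27 ± 0.86 and 1.93 ± 0.24. Tl-like stood at 7.69 ± 2.98 against 11.2 ± 4.38. All of these lie within 1 SD of the uninfected means, so their calls do not show a decline in TPM. Only 1 of the 14 had every infected library below every uninfected one. Both Cactus models and Pellino rose 3.87-fold, 3.91-fold and 3.03-fold. Of the 9 IMD and JNK genes kayak rose 3.86-fold, and 5 others were called at ratios between 1 and the table's median. None of the 5 JAK-STAT genes was called at any of the 6 times by the authors' deposited p, which was 0.093 for hopscotch at 7 days, when it stood at 13.6 ± 3.68 against 4.31 ± 2.61 TPM. By the bounds, though, 3 of these 5 had every library at 7 days above every uninfected one. The JAK-STAT list's median log2 change was 1.04, close to the table's median of 0.93, so the absence of calls does not mean unchanged TPM. Several called genes had ratios close to 1: UbcC, the immunity gene of highest mean in uninfected larvae, stood at 698 ± 82.9 against 737 ± 224 TPM, and the authors' deposited p was 0.0001. Of 34 genes with a log2 change within 0.5 of 0, 25 were called, and of 19 between 0.5 and 1.5, 17 were not.

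**Figure D1:**
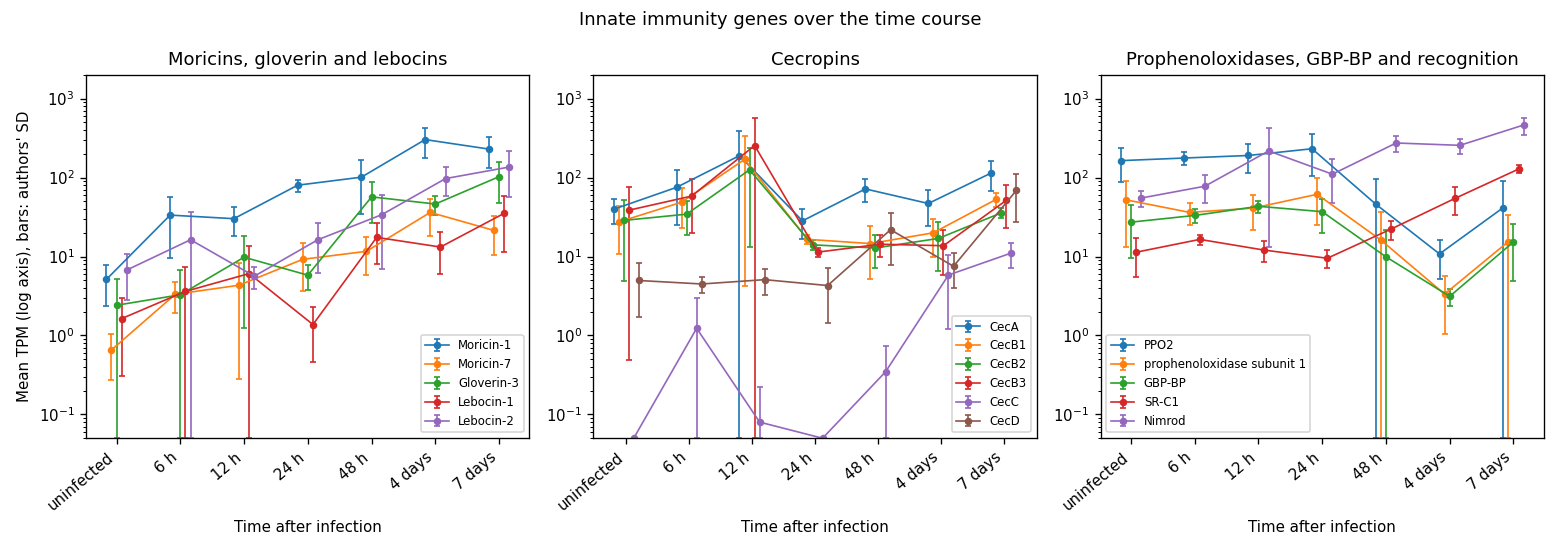
Mean TPM (log axis) of innate immunity genes in uninfected larvae and at 6 times after infection, with bars for the authors' SD over 3 libraries; bars that would pass the lower edge, and means of 0, are drawn at that edge. Moricin-1 climbed from 5.13 to 303 TPM at 4 days, the cecropins CecA and CecB1 to CecB3 were highest at 12 h with wide bars, and PPO2 dropped from 164 to 10.8 TPM at 4 days.

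**Figure D2:**
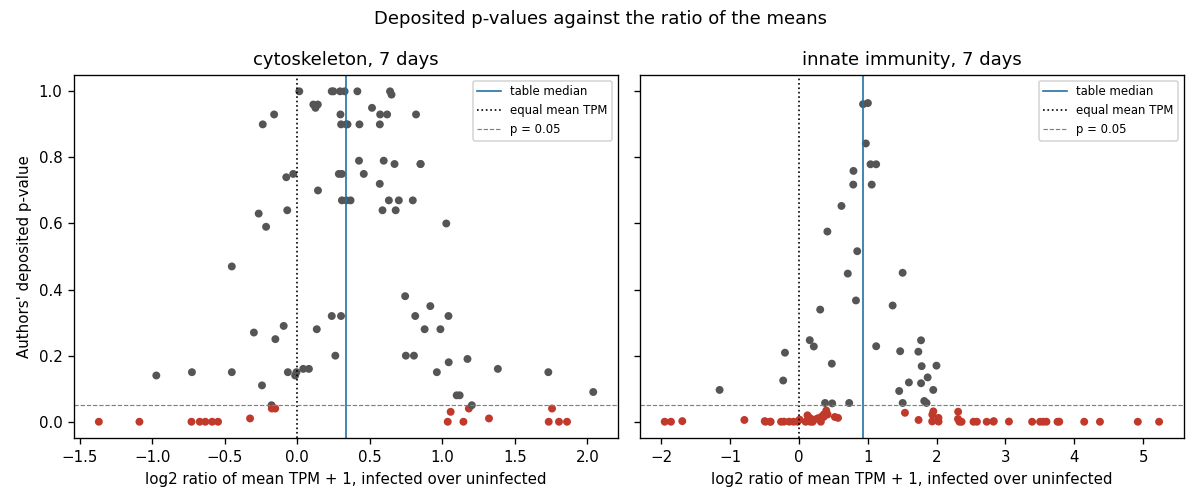
Each point is a gene of the cytoskeleton table (left) or the innate immunity table (right) at 7 days, with the log2 ratio of mean TPM + 1 on the horizontal axis and the authors' deposited p-value on the vertical one. Red points lie under 0.05, and the blue line marks the table's median, 0.34 and 0.93, beside the dotted line of equal means; of 34 innate immunity genes within 0.5 of equal means 25 were called.

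The mitochondrial table sums to 1000000 in every group, so its values are shares among 38 mitochondrial features and a rise of 1 feature lowers the others. Of the 15 protein and rRNA genes, 0 passed the deposited test at 6 h, 12 h, 24 h, 48 h and 4 days. At 7 days ATP6, a subunit of the ATP synthase, fell from 113711 ± 24226 to 64974 ± 2787 TPM, 1.75-fold, with every infected library below every uninfected one and a p that the authors' deposited table gives as 0. The 12S rRNA rose 3.10-fold, from 494 ± 201 to 1531 ± 1064, and the authors' deposited p of 0.01 became 0.08 when adjusted over the table. ATP8, whose gene adjoins ATP6, stood at 2692 ± 3369 against 2807 ± 3503 TPM.

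The cytochrome oxidase subunits COI, COII and COIII had the greatest shares at 7 days, at 383807 ± 34269, 110888 ± 9585 and 192470 ± 7849 TPM against 378352 ± 62319, 98142 ± 4784 and 164880 ± 21609, and none of the 3 was called. CYTB stood at 77316 ± 12955 TPM at 7 days. At 48 h it was at 69359 ± 8166 against 99120 ± 14920, with all infected libraries below all uninfected ones although the authors' deposited p was 0.09. Of the 7 complex I genes 0 were called at any time. ND1, ND3, ND2, ND6 and ND4L were at 1.02-fold, 1.25-fold, 1.16-fold, 1.25-fold and 1.21-fold of uninfected larvae at 7 days, and ND4 and ND5 were 1.23-fold and 1.25-fold lower. The 16S rRNA stood at 73155 ± 28186 TPM against 57389 ± 66146. Libraries were made from polyadenylated RNA, which bears on the rRNAs and on the 22 tRNAs, for which the tables give no p.

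**Figure D3:**
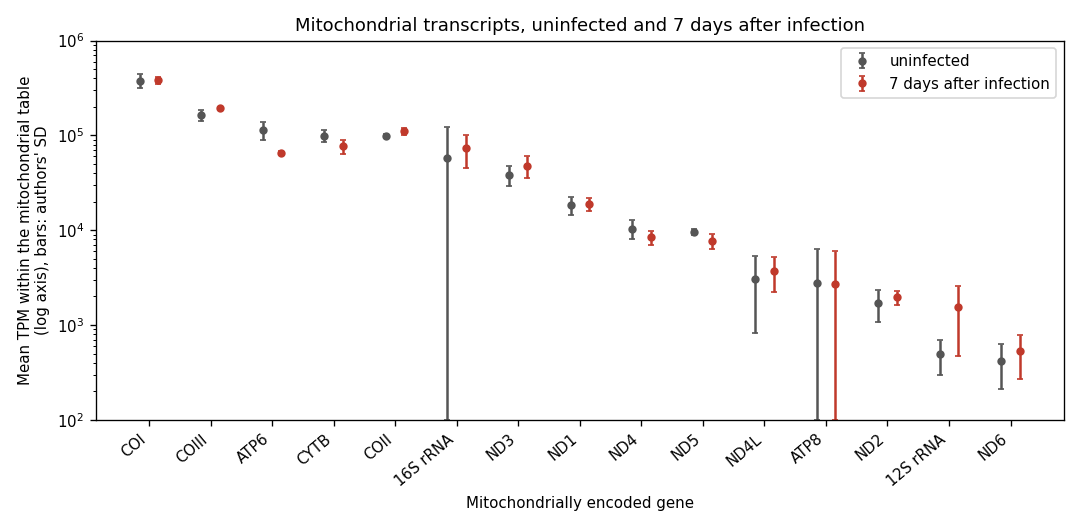
Mean TPM within the mitochondrial table (log axis) of the 15 protein and rRNA genes in uninfected larvae (grey) and 7 days after infection (red), with bars for the authors' SD over 3 libraries, cut at the lower edge where they would pass it. ATP6 lies at 113711 TPM in uninfected larvae and at 64974 at 7 days, and the bars of most other genes overlap.

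Among 106 cytoskeleton genes few were called early: 1 fell at 6 h and 3 fell at 12 h, with 0 risen, and none of these passed when adjusted over the table. A gene model named dystonin/microtubule-actin cross-linking factor 1-like (GSSPFG00017442001) fell 4.58-fold at 6 h and 4.33-fold at 12 h from 23.3 ± 20.1 TPM. A second model of that name (GSSPFG00032091001) fell 3.26-fold at 12 h, as did the kinesin KIF21B by 3.42-fold. These proteins link or move along microtubules. The median log2 change was -0.18 at 6 h and -0.16 at 12 h.

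At 24 h, by the headings of the deposited p-values, which list 48 h before 24 h, 4 cytoskeleton genes rose and 2 fell. Gamma-2 tubulin, which nucleates microtubules, rose from 4.30 ± 0.387 to 9.05 ± 1.78 TPM, and KIF23, a motor of the central spindle in dividing cells, rose 2.51-fold to 2.18 ± 0.370. In both, every infected library lay above every uninfected one. The chromosome-associated kinesin KIF4 rose 2.02-fold and gamma-tubulin complex component 3 rose 1.38-fold, so that 4 of 64 genes of the microtubule list rose and 1, the tubulin polyglutamylase TTLL4-like, fell 1.59-fold. Myosin-IIIb-like fell 2.30-fold and was the 1 of 40 genes in the actin list that was called. Adjusted over the table, only gamma-2 tubulin and KIF23 passed of the 6, each with an authors' deposited p rounded to 0.

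At 48 h 4 microtubule genes rose, gamma-tubulin complex component 3 by 2.36-fold, KIF23 by 3.00-fold, KIF4 to 13.6 ± 4.11 TPM against 3.65 ± 0.948 and gamma-2 tubulin to 11.3 ± 3.96, while cofilin, an actin-severing protein, fell 1.45-fold and lamin-C of the nuclear envelope 1.35-fold. Of these 6 called genes gamma-tubulin complex component 3, KIF4 and lamin-C passed when adjusted over the table, each with an authors' deposited p rounded to 0. The median log2 change of the table was 0.27. Several microtubule genes had nearly all of their 48 h TPM in 1 library, and means do not show whether it was the same one for each. Tubulin alpha-8 stood at 28.5 ± 47.7 TPM against 6.08 ± 2.92, and its highest library must hold at least 97.7% of the total.

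At 4 days, 8 cytoskeleton genes rose and 6 fell, and 7 of the 8 belong to the microtubule list. KIF4 stood at 13.6 ± 6.16 TPM, 3.72-fold above uninfected larvae, gamma-2 tubulin at 13.8 ± 3.07, KIF23 at 3.66 ± 0.724 and the spindle motor Klp61F at 8.94 ± 3.96 against 2.62 ± 1.21. Gamma-tubulin complex component 2 rose 2.80-fold to 10.3 ± 0.506 and KIF18A 2.99-fold. All of these had every infected library above every uninfected one. Actin-related protein 2, a nucleator of actin branches, rose 1.90-fold. Lamin-C fell 1.39-fold to 105 ± 5.19 TPM, a cytoplasmic dynein 1 intermediate chain (GSSPFG00012793001) fell 2.37-fold and myosin-IIIb-like 2.35-fold. Of the 14 called genes 9 passed when adjusted over the table, and 7 microtubule genes passed when adjusted over the list alone.

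At 7 days, 9 cytoskeleton genes rose and 10 fell, and the table's median log2 change was 0.34. The 2 most abundant transcripts of the table fell: myosin regulatory light chain 2 from 10864 ± 2016 to 5112 ± 996 TPM, 2.13-fold, and myosin light chain alkali from 9723 ± 1437 to 5867 ± 1078, 1.66-fold, each with no overlap between libraries. Muscle myosin heavy chain, the 1 measured gene of the fixed muscle marker list, was not called and stood at 2958 ± 375 against 2399 ± 1420 TPM. That list names no myosin light chain, and 1 gene does not show whether muscle transcripts as a whole changed. Filamin-A (GSSPFG00031717001), an actin crosslinker, fell 2.65-fold and lamin-C 1.46-fold. Of the 40 genes of the actin list 4 rose and 7 fell, and 8 passed when adjusted over the list alone.

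The 4 that rose include non-muscle myosin heavy chain, the motor of contractile actin bundles, whose models GSSPFG00012506001 and GSSPFG00023985001 rose 3.58-fold to 101 ± 32.5 and 3.52-fold to 59.7 ± 34.0 TPM, and a myosin-I heavy chain (GSSPFG00013835001), 4.80-fold. Laminin subunit gamma-1, a basement membrane protein outside both lists, rose 3.96-fold to 31.7 ± 11.4. Of the 64 genes of the microtubule list 4 rose, KIF23, KIF4, gamma-tubulin complex component 3 and a cytoplasmic dynein heavy chain (GSSPFG00002018001.1), by 3.61-fold, 2.62-fold, 2.30-fold and 2.63-fold, and 3 fell. Gamma-2 tubulin, at 11.2 ± 1.90 TPM with every library above the uninfected ones, did not pass, its p in the authors' deposited table being 0.05. Of the 19 called genes 12 passed when adjusted over the table.

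**Figure D4:**
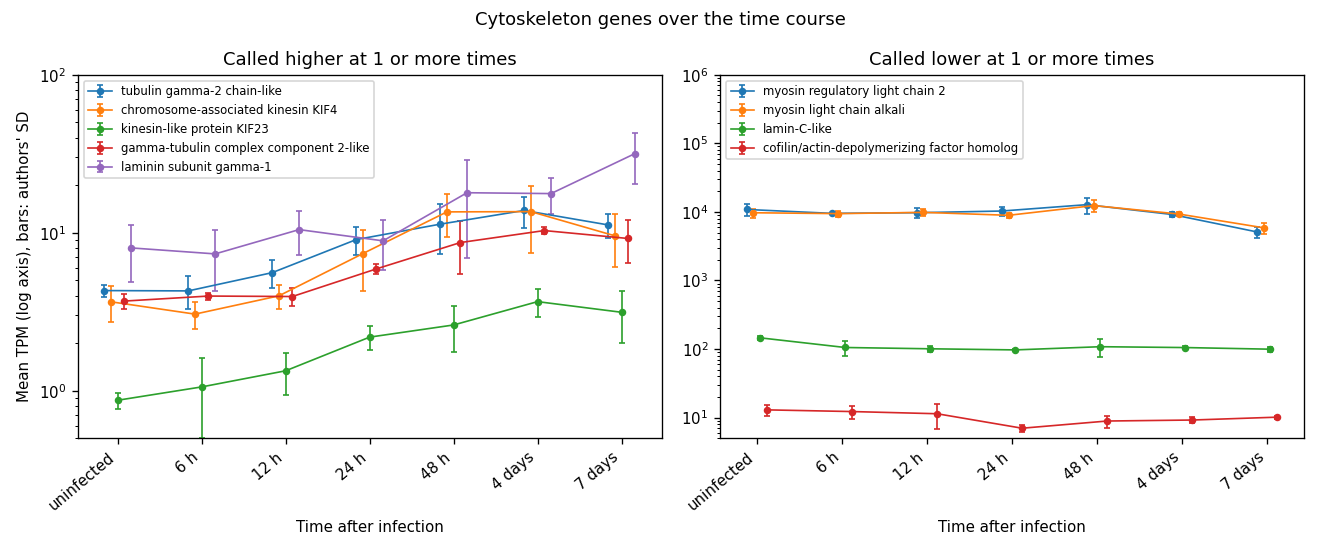
Mean TPM (log axis) of 9 cytoskeleton genes in uninfected larvae and at 6 times after infection, with bars for the authors' SD over 3 libraries, cut at the lower edge where they would pass it. Gamma-2 tubulin climbed from 4.30 to 13.8 TPM at 4 days and KIF4 from 3.65 to 13.6, while myosin regulatory light chain 2 stayed between 9190 and 12759 TPM up to 4 days and stood at 5112 at 7 days.

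Across the 6 times, 72 of 97 immunity genes, 29 of 106 cytoskeleton genes and 2 of 38 mitochondrial features were called at 1 or more times. Without the 48 h group, in which several genes had nearly all of their TPM in 1 library, not known to be the same one, the counts are 68, 29 and 2. By the bounds from mean and SD alone, 47 immunity genes (48.5%) and 33 cytoskeleton genes (31.1%) had all libraries at 7 days beyond all uninfected ones. Chance gives 10% for 3 libraries against 3 whose values are known, and by these bounds 4.58% and 6.12% of genes simulated without a change. Of the 47 immunity genes 46 lay higher, and of the 33 cytoskeleton genes 29, and the bounds take no account of the tables' median shifts of 0.93 and 0.34.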

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

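The tests in this part were chosen after the results were seen. Groups of 3 libraries are too small for a test of single outlying libraries, and library values were not analysed here.

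In 9 genes all libraries of 1 time lay below, and all libraries of another above, the uninfected ones, by the bounds from mean and SD. The difference between the times was not tested, and the same uninfected libraries stand in both. The PGRP gene GSSPFG00026857001.5 had a log2 change 3.31 higher at 7 days (99.3 ± 29.8 TPM) than at 24 h (9.10 ± 1.63), against 27.4 ± 13.7 in uninfected larvae. The gap between 7 days and 12 h was 2.93 for Eater-partial (GSSPFG00035226001.3), 2.49 for Cactus (GSSPFG00001145001.2) and 1.78 for Tollip. Between 7 days and 6 h it was 2.68 for Hdd23 (GSSPFG00035416001.3) and 2.41 for HP8. Between 4 days and 12 h it was 1.43 for c-jun and 0.95 for Myd88, and between 7 days and 24 h it was 0.53 for actin-related protein 2/3 complex subunit 2.

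The kinesin KIF19 has no deposited p at 12 h or 4 days, yet its libraries lay above all uninfected ones at both: 9.37 ± 7.51 and 0.367 ± 0.0808 TPM against 0.123 ± 0.102. At 48 h it stood at 6.11 ± 9.82 TPM with at least 95.1% in 1 library.

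The cecropins at 12 h were higher with SDs near or above their means. Mean and SD force the highest library to hold at least 57.6% of the group's TPM for CecB2, 65.0% for CecB1, 71.6% for CecA and 80.3% for CecB3. In uninfected larvae the same bound gives 49.3%, 45.0%, 40.1% and 65.8%, so an uneven spread of CecB3 is not particular to 12 h. These shares restate the SDs and explain nothing. That the higher mean comes from 1 library alone is argued against for CecA, CecB1 and CecB2. Their other 2 libraries average at least 71.1, 74.1 and 60.5 TPM, above the most that any uninfected library can hold, 55.8, 46.5 and 56.0. For CecB3 the other 2 average at least 70.0 TPM against at most 82.5 in an uninfected library, which leaves it open. A larva that responded more strongly than the others, or one that carried another microbe, may be behind the spread, which was not tested. Whether the CecB genes share reads was not tested either.

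At 48 h, 15 cytoskeleton genes had over 80% of their TPM in 1 library, against 4 to 10 in the other groups. Means and SDs do not say which library this was for any gene, nor whether it was the same one. Among them are tubulin alpha-8 (28.5 ± 47.7 TPM), tubulin alpha-1 (20.9 ± 35.6) and a tubulin glycylase (2.59 ± 3.86). A 48 h library aberrant throughout is argued against by the other genes, whose median SD over mean was 0.288 at 48 h and between 0.194 and 0.389 elsewhere. These leave out axonemal names and every gene with over 80% in 1 library, which lowers the median. Over all genes above 0 TPM it was 0.355 at 48 h and between 0.227 and 0.399 elsewhere. A moderate shift of a whole library is not excluded by these values. Low values stay open: among genes of at least 5 TPM in uninfected larvae 2 of 57 had over 80% in 1 library at 48 h, against 13 of 47 lower ones. This split by uninfected mean replaced one by the 48 h mean, which each gene's dominant library itself sets. A tissue with axonemes, such as testis, in 1 larva may contribute, which needs the same library to be highest in each gene, and that was not testable here. Of 11 genes counted as axonemal or ciliary by name, 6 had over 80% in 1 library, against 6 of 28 other low genes (one-sided Fisher's exact p = 0.0537, adjusted over the 6 times 0.116). The set counts tubulin glycylases, which are among the 6 and whose names say neither axonemal nor ciliary, so the test holds only for this wider set. The same test at 7 days, with the same wider set of names, gave 6 of 10 against 2 of 28 (exact p = 0.00169, adjusted 0.0102). Here too low genes were picked by the mean of the tested group, and when picked by the uninfected mean, a step added later, the others numbered 7 of 37 at 48 h (exact p = 0.0290, adjusted 0.0871) and 3 of 38 at 7 days (0.00111, adjusted 0.00665). The 6 axonemal names at 7 days had means between 0.02 and 0.577 TPM, where reads in 1 library alone give such a share. The other low genes reach up to 5 TPM, so level and name are mixed in the comparison. All genes come from the same larvae and are not independent, which these p-values leave out of account. The 48 h test falls on either side of 0.05, and neither time decides on a tissue with axonemes.

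The deposited p-values of immunity genes at 7 days are arranged about a raised TPM ratio: the log2 ratio from which p falls most steadily on both sides was 1.10 (95% bootstrap interval over genes 1 to 1.20), where 0 would be equal means. One factor shared by all genes of a library, such as viral transcripts taking part of each, is argued against as the only cause. The cytoskeleton table's centre lay at 0.40, 0.70 lower (interval 0.60 to 0.80). That centre is itself above 0 (interval 0.35 to 0.50), so a smaller shared factor is not excluded. The comparison also takes the 2 tables to have been tested alike, which is not known. Low values and the pseudocount are argued against by the centre of 1.15 (1.05 to 1.25) among genes of at least 5 TPM with no pseudocount. That each test was centred on the genes of its own table was tested first by whether the table's median lay inside the interval of the centre, which held in 0 of 4 cases (both tables at 4 and 7 days). Outside these 4 it held for the cytoskeleton table at 48 h (median 0.27, interval 0.25 to 0.35) and for immunity genes at 7 days of at least 5 TPM with no pseudocount (median 1.18, inside the interval 1.05 to 1.25 given above), and not for the immunity table at 48 h (0.33, interval 0.40 to 0.50). Centring on the plain median is thus neither shown nor excluded. A second test, added only after that result and with the criterion widened then, resampled both, and the interval of centre minus median held 0 in 3 of the 4. Centring of some kind on the table's genes thus stays open, on the weaker footing of a test added late. If it took place, a call may say that a gene moved otherwise than its table, not that its share of the larva's RNA changed.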

How the results depend on the processing

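Tests marked here as added were chosen after the data were seen; the others were planned before the data were examined. No paired analysis was possible because the tables hold group means only, so limma, its F test and intensity trend, a replicate block, fits of 2 groups or of all tables, leaving out replicates, centring per library and permutation of list means were not run. Pseudocount 5 and filters on the mean over all groups, planned for that fit, were not run either.

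Of 136 results for named genes, pseudocount 0.1 turned the direction of 0, and no pseudocount turned 0 of the 135 it could give. A pseudocount cannot change which of 2 means is higher, so these values of 0 were fixed beforehand and lend no support. Dividing by the table's median ratio turned 5, none of them called. Adjusted over the table, 33 lost the call. The TPM minimum of 5 left every count within 1.5 times, as did the added limit that the SD not exceed the mean and, over all times, leaving out 48 h.

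Benjamini-Hochberg adjustment over the table lowered the cytoskeleton counts of 1, 3, 6, 6, 14 and 19 called genes at the 6 successive times to 0, 0, 2, 3, 9 and 12. A p under 0.01 gave the same numbers because, at 2 decimals, both settings keep only genes deposited as 0. That agreement is fixed by the rounding and lends no support. For immunity genes the counts of 5, 20, 11 and 31 from 6 h to 48 h became 1, 13, 5 and 10 when adjusted, and p under 0.01 gave 2, 12 and 25 at 6 h, 48 h and 4 days, the last from 41. Requiring also that all libraries lie beyond the uninfected ones (added) left 0, 0, 2 and 11 cytoskeleton genes at 6 h, 12 h, 24 h and 7 days and 1, 8, 6, 12, 25 and 28 immunity genes at the 6 times, the last from 58. The 2 mitochondrial calls at 7 days became 1 under each of these 3 settings. Over all times, 29 cytoskeleton genes became 17 under adjustment per time or over all times, p under 0.01 or separated libraries, 72 immunity genes became 44 with separated libraries, and 2 mitochondrial features became 1. These settings only remove calls by construction.

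Dividing by the table's median ratio moved the share of called immunity genes with the higher mean at 7 days from 77.6% to 46.6%, and the mitochondrial list and time pairs with a median above 0 from 14 to 5 of 18; the cause was not tested beyond the shift itself. Depth is unknown, so what it limits cannot be stated.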

Other observations

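The tests in this part were chosen after the data were seen.

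The antimicrobial peptide Def-like6 went from 140 ± 75.6 TPM in uninfected larvae through 352 ± 96.9 at 48 h and 663 ± 102 at 4 days to 816 ± 37.8 at 7 days, and Spod_x_tox, in none of the fixed lists, from 0.253 ± 0.170 to 6.52 ± 2.42 at 7 days. POI rose 12.2-fold to 142 ± 68.6 and p77 7.47-fold to 11.8 ± 4.92 at 7 days, each with every library above the uninfected ones. Both eater models, named for a phagocytosis receptor, stood at 22.2 ± 5.20 and 14.5 ± 3.81 TPM in uninfected larvae. They were called at 48 h, at 18.2 ± 5.82 and 12.9 ± 4.22, which lie within 1 SD of the uninfected means, so a dip is not shown. At 7 days they were called higher, at 119 ± 10.7 and 76.9 ± 9.60. GBP rose 2.27-fold to 413 ± 87.2 TPM at 12 h and stood at 183 ± 75.6 at 7 days against 182 ± 54.7, while GBP-BP fell from 27.2 ± 17.8 TPM to 3.13 at 4 days. The Hdd23 models GSSPFG00035032001.3 and GSSPFG00035416001.3, not called at 7 days, stood at 242 ± 79.3 and 141 ± 46.2 TPM then against 70.0 ± 21.1 and 35.7 ± 5.29 in uninfected larvae.

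Tubulin-folding cofactor B stood at 1.21 ± 1.62 TPM at 24 h against 8.73 ± 1.64, with all libraries below the uninfected ones, while the authors' deposited p was 0.1. Both tubulin beta chain models were highest at 48 h, at 90.9 ± 103 and 49.9 ± 42.5 TPM against 25.8 ± 8.70 and 15.9 ± 6.36. Profilin, an actin-binding protein, stood at 1005 ± 273 TPM at 4 days against 589 ± 68.9.

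A hypothesis is that genes of microtubule nucleation and cell division move together with time after infection. The values compared are those of 11 genes picked by name (gamma-2 tubulin, gamma-tubulin complex components 2, 3, 4 and 6, KIF4, KIF23, Klp61F, KIF18A, Klp10A and anillin) and of the other 95 cytoskeleton genes. At 7 days their mean log2 change was 0.55 higher (0.89 against 0.35), with 11 of 11 above 0. At 4 days the gap was 1.02, at 48 h 0.60, at 24 h 0.55, at 12 h 0.18 and at 6 h 0.07. The set was chosen after members had been seen to rise, and 7 of the 11 were called at 1 or more times, so the gaps partly restate that choice and a permutation over genes, which was run, decides nothing. Growth of the larvae with age may give the same course, and with no uninfected larvae of matched age it cannot be told apart from infection.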
